A study of Mus musculus with 3 samples.

How the data were processed

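Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on limb buds of C57BL/6 mouse embryos at embryonic day 12.5. Per the labels, fore- and hindlimb buds were pooled, in 2 runs of 48 limb buds each. The frozen tissue was fixed with 1% formaldehyde for 15 min while it thawed, and the chromatin was sheared to 300 to 500 bp. From 30 µg of chromatin, LMX1B was precipitated with 20 µl of the polyclonal antibody BMO8, and the libraries were sequenced on an Illumina NextSeq instrument. The labels name the same antibody for both ChIP samples and do not say whether these came from separate chromatin preparations. The input DNA, from pooled wild-type and mutant chromatin per the labels, had no interval list and entered no test.

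Per the submitters' processing notes, BWA was used and the genome build was mm10. The peak caller, its threshold and the version of BWA are not given in the sources used here. Each ChIP sample had 1 list of intervals (peaks) made by the authors and a summit with a whole-number score per interval. The deposited score has no stated unit or normalization. It was used to describe, rank or filter intervals within its own list, and scores of shared pairs were correlated between the lists. In a test on chromosome X, autosomal scores were also halved, which assumes a scale that the sources do not state. Sequencing depth is unknown, since interval lists carry no read counts. Intervals were tied to samples by the track names in the deposited lists. The track name of the first ChIP marks its limb buds as wild-type (WT), while that of the validation ChIP gives no genotype. The deposited lists of the validation sample also repeat all 1287 intervals of the first ChIP, identically except that 1 summit on chromosome 1 moved by 16 bp; the copy was counted once. Coordinates are given from 1 on mm10.

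Intervals were called shared when they overlapped an interval of the other list by at least 1 bp. The count was compared with 1000 random placements of the validation list, which kept each interval's chromosome and width, with a one-sided permutation p. Placements ran from 3 Mb on autosomes and X to the last annotated gene or interval; assembly gaps were not avoided otherwise. Summit scores were compared by the median of shared and unshared intervals within a list, with a two-sided permutation test of 100000 resamples. Clustering was counted as shared intervals with another within 50 kb, again against 1000 placements.

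Gene positions came from a RefSeq table of assembly GRCm38.p6, whose chromosome coordinates are those of mm10. It held 49603 genes after 340 entries that start before 3 Mb were left out, 21779 of them protein-coding. The table has gene starts and ends but neither strand nor exons. Transcription start sites, exons and introns were therefore not resolved, and the planned location classes and regulatory domains were replaced. Interval midpoints were classed as within 1 kb of either gene end, elsewhere in a gene body, or outside genes. They were compared with 1000 placements by two-sided permutation tests, with Benjamini-Hochberg adjustment over 9 tests. A gene's domain was its body extended both ways to the next protein-coding gene body, at most 1 Mb. For 16 gene lists fixed before the data were examined, the number of members with a shared interval in their domain was compared with 10000 random lists. The random lists were matched on domain length in 20 bins, with two-sided permutation p-values adjusted by Benjamini-Hochberg over the 16 lists. The lists covered dorsoventral limb patterning, small leucine-rich proteoglycans, limb transcription factors, limb signalling, joint, cartilage, tendon and connective tissue, and axon guidance. Others held genes linked to Lmx1b outside the limb, muscle, endothelium, blood, ectoderm, nerve and Schwann cells, housekeeping genes, and adult liver and gut genes as a control.

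The genes named were set by a rule: the 10 shared intervals with the highest validation score, at most 5 members per list by distance to the nearest shared interval, and Lmx1b and Gdf5. Distances run from the midpoint of the first-ChIP interval to the nearer gene end, in place of the start site. The rule also held that, with no genome of the build, names would come from the files alone; since a gene table of the same assembly was used, its names are given. Motif content, motif position and k-mer tests were planned for 26 motifs and were not run, because no genome sequence was used here.

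Alternatives were stricter overlap rules, intervals at or above the median score, local placement, other gene windows and other list backgrounds. The overlap and list functions were tested on simulated data. With 300 planted overlaps among 1287 intervals, 303 were found. Of 200 random lists of 40 genes, 3 had an unadjusted p under 0.05, and all 200 lists with 15 occupied members did. The random lists were drawn from all protein-coding genes. Lists of long domains and smaller excesses were not simulated. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.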

Results

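LMX1B is the LIM homeodomain protein that gives the limb its dorsal character. Its chromatin occupancy was recorded in limb buds at embryonic day 12.5 in 2 ChIP-seq samples with 1 antibody. One is called the first ChIP here and the other, which its title calls a validation of BMO8, the validation ChIP. Each is a single sample, so there are no replicates within a group and no spread between replicates. The tests below treat intervals or genes as units, which are not independent replicates, and describe these lists. The first ChIP listed 1287 intervals with a median width of 389 bp, and the validation ChIP 4501 with a median of 571 bp.

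Whether the same sites were listed in both samples was asked first. Of the first-ChIP intervals, 707 (54.9%) overlapped 701 (15.6%) of the validation intervals. Random placement gave a mean of 2.54 and at most 10 overlaps in 1000 placements (one-sided permutation p = 0.001, the smallest they can give). Placement within 1 Mb of the original position gave a mean of 5.98 and at most 14. Summits of the 707 pairs lay a median of 64 bp apart, and 523 pairs (74.0%) were within 100 bp. With overlap of at least 50% of both intervals, 461 intervals were shared.

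The shared interval with the highest validation score, 55, lay on chromosome 19 at 56086303 to 56087450, outside genes, 153 kb from Tcf7l2, which encodes a nuclear effector of Wnt signalling. The next lay in Dnm3 on chromosome 1 at 161983776 to 161984763, with scores of 51 in the validation ChIP and 54 in the first. Intervals in Pard3b (chromosome 1, 61927902 to 61929142), Jakmip3 (chromosome 7, 139012585 to 139013490) and Pam (chromosome 1, 97974676 to 97975512) each had a validation score of 50. Those in Dclk1 (chromosome 3, 55496279 to 55497094), Atg10 (chromosome 13, 91187135 to 91188093) and Bend4 (chromosome 5, 67400593 to 67401488) had 49, 48 and 44. The interval in Atg10 also had the highest score of the first ChIP, 86. The last of the 10, both with 43, lay outside genes: one on chromosome 2 (171734100 to 171735914), 301 kb from Cbln4, and one on chromosome 18 (68910369 to 68911743), 432 kb from Tcf4. Thus 7 of the 10 lay in the body of a protein-coding gene; whether in exons or introns was not resolved.

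Shared intervals had higher scores than unshared ones within each list. The median score in the first ChIP was 22 for shared and 18 for unshared intervals, and in the validation ChIP 16 and 11 (two-sided permutation p = 1e-05 for each, the smallest 100000 resamples can give). In the first ChIP the shared percentage was 26.1% (95% Wilson interval 21.5 to 31.2) at scores of 12 to 17 and 79.8% (74.1 to 84.6) at 26 to 86. In the validation ChIP it was 3.61% (2.65 to 4.89) at scores of 6 to 9 and 48.5% (45.0 to 52.1) at 16 to 55. Across the 707 pairs, scores in both lists correlated with a Spearman rho of 0.406 and a Pearson r of 0.420 (permutation p = 1e-05 for each). Without the 2 pairs farthest from the median first-ChIP score, Pearson's r was 0.418.

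**Figure D1:**
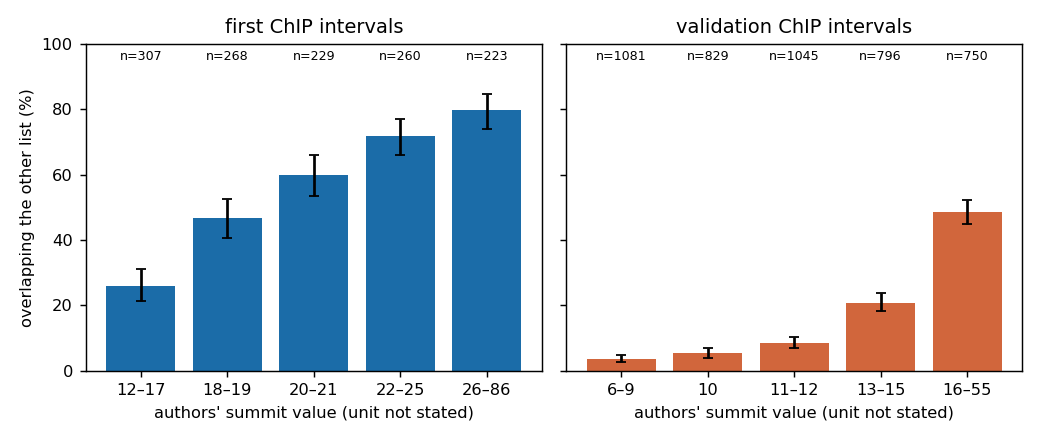
Percentage of intervals that overlapped the other list (vertical axis) by the authors' summit score (horizontal axis, unit not stated), for the first ChIP (left) and the validation ChIP (right). Error bars are 95% Wilson intervals and n is the number of intervals; the percentage was 26.1% in the lowest and 79.8% in the highest group of the first ChIP.

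Lmx1b itself (chromosome 2, 33560965 to 33641208) had 3 shared first-ChIP intervals in its domain. Of 21779 protein-coding genes, 73 had at least as many. They lay between Lmx1b and Mvb12b, at 33700481 to 33701323, 33701591 to 33701930 and 33705754 to 33706277, with first-ChIP scores of 38, 20 and 19. The nearest was 59.7 kb from Lmx1b. The first pair overlapped 1 validation interval with a score of 41, and the last overlapped one with 26. None of the 3 had a validation midpoint within 250 bp of its own. A further first-ChIP interval at 33486606 to 33486955 was not shared. Of the 7 validation intervals in the domain, 5 were not shared: at 33615444 to 33616364 in the gene body (score 12), at 33641016 to 33641350 across the gene end (10), and at 33682229, 33716508 and 33718742 beyond it (8, 10 and 17). Gdf5 (chromosome 2, 155941023 to 155945367), which encodes a joint-forming growth factor, had no interval of either list in its 26.0 kb domain. Within 300 kb, 2 shared intervals lay at 155862829 to 155863721 and 156180244 to 156180515, nearer to other genes. The first was 77.7 kb and the second 235 kb from Gdf5. The domain stops at the neighbouring genes Uqcc1 and Cep250, so intervals beyond its borders could not count for Gdf5. An empty domain therefore does not show that Gdf5 has no interval of its own.

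**Figure D2:**
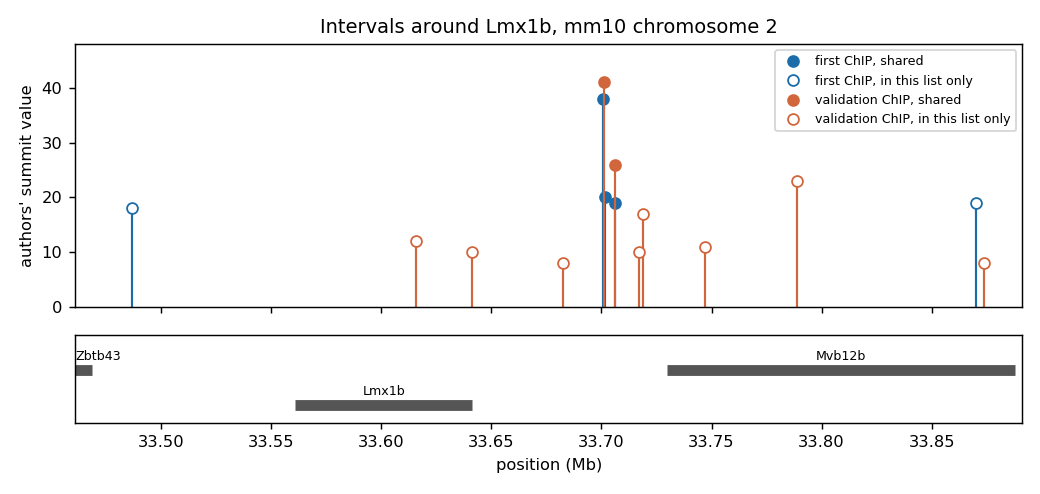
Authors' summit score (vertical axis, unit not stated) of each interval around Lmx1b against its position on mm10 chromosome 2 in Mb, with gene bodies drawn below. Filled circles are shared and open circles unshared; the highest, 41 in the validation ChIP and 38 in the first, lie between Lmx1b and Mvb12b.

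Genes of limb development were next compared with genes of matched domain length. Limb transcription factors had a shared interval in 18 of 48 domains, where 5.21 were expected (3.45-fold, two-sided permutation p = 0.0002, adjusted permutation p = 0.0032). Among them were Prrx1 and Hoxa9, with an interval 0.262 kb and 0.965 kb inside a gene end, and Prrx2, Zfhx3 and Msx1, at 11.3, 16.4 and 71.0 kb. Prrx1 had its interval on chromosome 1 at 163314747 to 163315020, and Hoxa9 on chromosome 6 at 52225975 to 52226836. Tendon and connective tissue genes had one in 9 of 34 domains, where 3.05 were expected (2.95-fold, permutation p = 0.0038, adjusted permutation p = 0.0304). These included Fbn2 (3.68 kb from a gene end), Ebf3 (14.5 kb), Col1a2 (15.8 kb), Eya1 (22.7 kb) and Eya2 (28.1 kb). Fbn2 encodes a fibrillin and Col1a2 a chain of type I collagen. The remaining occupied members were Tcf4, Tcf7l2, Ebf1 and Six2, which like Ebf3, Eya1 and Eya2 encode transcriptional regulators. Tcf4 and Tcf7l2, which are different genes, had the most shared intervals of the list, 5 and 4. Whether Tcf4 belongs with tendon and connective tissue genes was not examined, and the list was not tested without it. The tendon and matrix genes Scx, Mkx, Tnmd, Col1a1 and Tnc had none in their domains. With a window of 50 kb around the gene the tendon list did not pass, with fewer occupied members (6 of 34 against 1.64 expected, 3.65-fold, adjusted permutation p = 0.0608).

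The other limb lists did not pass adjustment. Axon guidance genes were occupied in 11 of 38 domains against 5.34 expected (adjusted permutation p = 0.104), with Gfra1, Robo1, Sema3d, Unc5c and Nrp2 at 15.0, 40.5, 58.7, 63.6 and 69.4 kb. Joint genes were occupied in 5 of 18 against 1.49 (adjusted permutation p = 0.0885): Sulf1 at 1.58 kb, Trps1 at 43.8 kb, Gdf6 at 63.8 kb, Osr2 at 88.7 kb and Osr1 at 170 kb. Dorsoventral patterning genes were occupied in 4 of 16 against 1.32 (adjusted permutation p = 0.189). Apart from Lmx1b these were Lrp6, a Wnt co-receptor, at 58.6 kb, En1, a ventral ectoderm gene, at 108 kb, and Ldb2, which encodes a LIM-domain binding protein, at 267 kb. The small leucine-rich proteoglycans Dcn and Lum, 2 of 15 against 0.303 (adjusted permutation p = 0.184), shared 1 interval on chromosome 10 at 97536797 to 97537322, 18.9 kb from Dcn and 28.4 kb from Lum. Limb signalling genes were occupied in 7 of 43 against 4.08 (adjusted permutation p = 0.453), with Bmp7, Aldh1a2, Bmp2, Jag1 and Rspo3 at 6.32, 41.3, 104, 132 and 190 kb. Cartilage genes were occupied in 3 of 30 against 1.68 (adjusted permutation p = 0.721): Nkx3-2 at 23.1 kb, Sox9 at 219 kb and Sox5 at 329 kb.

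Lists for other cell types and functions did not pass with shared intervals. Of genes linked to Lmx1b outside the limb, 1 of 20 was occupied (Nr4a2, 0.798 expected, adjusted permutation p = 1), and of muscle genes 0 of 19 (0.734 expected, adjusted permutation p = 1). Endothelium had 1 of 15 (Cdh5, 0.834 expected), ectoderm 1 of 22 (Grhl2, 0.909 expected) and nerve and Schwann cells 1 of 15 (Stmn2, 0.695 expected), each with an adjusted permutation p of 1. Blood had 2 of 15 (Runx1 and Ptprc, 0.740 expected, adjusted permutation p = 0.663). Housekeeping genes had 1 of 20 (Rps18, 0.231 expected, adjusted permutation p = 0.721) and adult liver and gut genes 0 of 20 (0.887 expected, adjusted permutation p = 1). The nearest shared interval lay 221 kb from Nr4a2, 795 kb from Cdh5 and 566 kb from Stmn2. It lay 438 kb from Runx1 and 690 kb from Ptprc, but 0.44 kb and 0.068 kb inside a gene end of Grhl2 and Rps18. Housekeeping genes passed with all intervals of the first ChIP (4 of 20, 6.53-fold, adjusted permutation p = 0.0363) and with all of the validation ChIP (6 of 20, 4.12-fold, adjusted permutation p = 0.0152). At these list sizes and expected counts, an excess of 4.32-fold (housekeeping) or 2.70-fold (blood) with shared intervals did not pass, while tendon genes passed at 2.95-fold. Not passing therefore does not show that an excess as large as that of the lists that passed is absent.

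**Figure D3:**
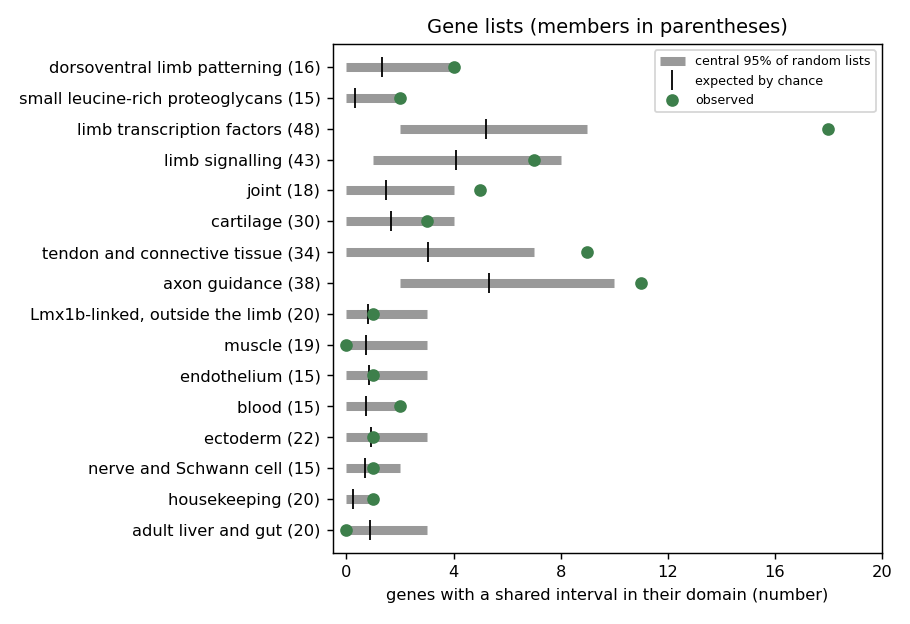
Number of genes with a shared interval in their domain (horizontal axis) for the 16 gene lists (vertical axis, members in parentheses). Green circles are observed counts, ticks the counts expected for lists of matched domain length, and grey bars the central 95% of random lists; limb transcription factors stand at 18 against 5.21 expected.

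Intervals lay at gene ends more often than chance in each list. In the first ChIP 27.6% of midpoints (95% Wilson interval 25.2 to 30.1) were within 1 kb of a gene end, against 6.40% in random placements. In the validation ChIP it was 16.2% (15.2 to 17.3) against 6.33%, and among shared intervals 15.3% (12.8 to 18.1) against 6.27% (adjusted permutation p = 0.00257 for each). Midpoints outside genes were below chance: 34.5%, 37.7% and 42.6% in the first, validation and shared sets, against 48.1%, 48.4% and 48.4% (adjusted permutation p = 0.00257 for each). The rest of gene bodies held 37.9% of first-ChIP midpoints against 45.5% (adjusted permutation p = 0.00257), 46.1% of validation midpoints against 45.3% (adjusted permutation p = 0.258) and 42.2% of shared ones against 45.4% (adjusted permutation p = 0.0877). For shared intervals, the share outside genes was 0.880 of chance. With protein-coding genes only it was 0.981 of chance (adjusted permutation p = 0.575). Among the 462 shared intervals at or above the median score it was 0.902 of chance, close to the value for all, but did not pass (adjusted permutation p = 0.0719).

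**Figure D4:**
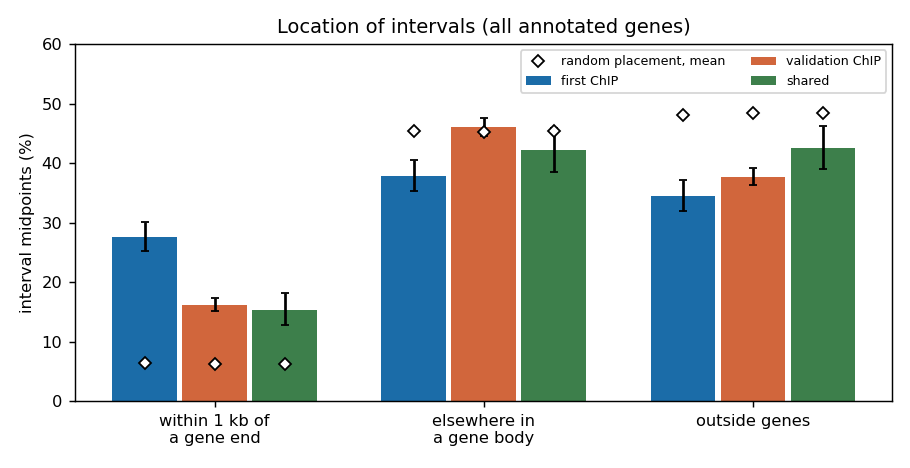
Percentage of interval midpoints (vertical axis) in 3 location classes (horizontal axis) for the first ChIP, the validation ChIP and the shared intervals. Error bars are 95% Wilson intervals and diamonds the mean of random placements; at gene ends the bars stand at 27.6%, 16.2% and 15.3%.

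Shared intervals gathered along the chromosomes. Of the 707, 135 (19.1%) had another within 50 kb, against a mean of 20.9 in random placements (6.47-fold, one-sided permutation p = 0.001, the smallest 1000 placements can give). Against placement within 1 Mb of the original position, the mean was 55.4 and the excess 2.44-fold (permutation p = 0.001). Within 10 kb the number was 57, against 4.27. The counts are of first-ChIP intervals. Neighbouring ones that overlapped the same validation interval, as the first pair near Lmx1b did, also count as clustered. How much of the excess came from such pairs was not examined.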

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

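The tests on actively transcribed genes and on weak signal were chosen after the results they bear on had been seen, and so were the comparisons of gene ends, ribosomal protein genes and abundantly transcribed genes between lists. The list of abundantly transcribed genes was also written after the data had been seen; it shares 9 genes with the housekeeping list and leaves out 1 gene already seen among the highest intervals, Cct4. The ChIP samples differed in where unshared intervals lay: 42.6% of first-ChIP-only intervals were within 1 kb of a gene end, against 16.3% of validation-only ones (Fisher's exact p = 3.19e-42). They differed also at 76 ribosomal protein genes, 40 of which had a first-ChIP interval within 1 kb and 16 a validation interval (exact McNemar p = 3.03e-06). Among the 10 highest first-ChIP-only intervals were those at Rpl32, Rpl5 and Rpl7a, with scores of 54, 53 and 51.

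Apart from active transcription, taken up below, no biological explanation was tested. Weak signal close to the calling limit of the first ChIP was argued against for the higher-scoring intervals only. With at least the median first-ChIP score of the shared intervals, 118 of the 580 first-ChIP-only intervals were compared with 365 shared ones. Of these, 64.4% and 14.8% lay at gene ends, in that order (Fisher's exact p = 5.21e-24). Weak signal in the validation ChIP could not be tested, since first-ChIP-only intervals have no validation score. Reads from processed copies or RNA cannot be told apart from other sources: 87.5% of 40 first-ChIP midpoints at ribosomal protein genes, shared ones included, were within 500 bp of a gene end, against 36.3% for random positions there (permutation p = 0.0001, the smallest 10000 draws can give). The prediction written beforehand took such an excess as evidence against this source, but terminal exons lie at gene ends too and exons were not resolved. Enrichment at very actively transcribed genes of any function may account for part of the pattern: of 59 abundantly transcribed genes that encode no ribosomal protein, 9, such as Ncl, Eef1a1 and Pkm, had a first-ChIP-only interval, 8.82 times the number for genes of matched length (permutation p = 0.0002). A difference between lists was not shown for these genes (exact McNemar p = 0.549). Of the 59, 6 had a validation-only interval (3.52-fold, permutation p = 0.0102). Of 76 ribosomal protein genes, 26 had a first-ChIP-only interval (21.6-fold) and 2 a validation-only one (1.21-fold). Shared intervals lay at 14 of the 76, where 0.365 were expected for genes of matched length (38.4-fold, permutation p = 0.0002). Validation intervals of any kind lay at 16 (7.996-fold, permutation p = 0.0002). The excess at ribosomal protein genes was therefore present in the shared set too, not only in first-ChIP-only intervals.

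A further deposited list, named Active Regions, held 735 regions, each identical to a first-ChIP interval. Of these 28 overlapped no validation interval but lay 5 to 499 bp from one, while the nearest first-ChIP interval outside the list was 533 bp away.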

How the results depend on the processing

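Settings chosen before the data were examined were applied to the replacement location classes and domains where start sites had been planned. Under them, 108 values for the main comparisons kept their direction and side of the threshold or, as counts, stayed within 1.5-fold. So did 43 chosen after seeing the data, which left out ribosomal protein genes or counted neighbouring list members once. No result past the threshold changed direction. Of results that passed in neither setting, 13 of the former values and 1 of the latter did, relative to expectation: endothelium, blood and nerve lists stood at 0 by nearest gene and within 50 kb, endothelium and genes linked to Lmx1b outside the limb at 0 with 50% overlap, and housekeeping genes at 0 without ribosomal protein genes. Endothelium stood at 0.761 and nerve at 0.871 with all first-ChIP intervals, endothelium at 0.617 and muscle at 1.29 with all validation intervals, and validation intervals in gene bodies at 0.995 with gene ends of 2.5 kb. The cause of these and the following changes was not tested. Shared first-ChIP intervals numbered 461 with overlap of at least 50% of both and 462 at or above the median score of each list, where fewer intervals were compared; 57 shared intervals were clustered within 10 kb. Relative to random placement, shared intervals stood at 0.867 in gene bodies (now past the threshold) and 0.981 outside genes (no longer past it) with protein-coding genes only, and 0.902 outside genes at or above the median score (no longer past it, with 462 instead of 707 intervals). The number of gene lists that passed was 2, and 1 with gene bodies within 50 kb, where tendon genes (3.65-fold) no longer passed. With all validation intervals 7 lists passed, adding dorsoventral (2.04-fold), limb signalling (1.99-fold), cartilage (1.90-fold), axon guidance (1.56-fold) and housekeeping genes (4.12-fold). With all first-ChIP intervals housekeeping genes passed (6.53-fold). Without matching on domain length 6 lists passed, adding dorsoventral (7.33-fold), limb signalling (4.77-fold), joint (8.14-fold) and axon guidance genes (8.49-fold). Axon guidance passed also by nearest gene (2.87-fold). For 41 named genes, 90 distances were the same and 9 moved to a farther interval. In 24 cases no shared interval was left: 11 genes with 50% overlap, such as Msx1, 2 with midpoints within 250 bp, Lmx1b and Trps1, and 11 at or above the median score, such as Prrx1 and Msx1. Alternatives for motifs and k-mers were not run. No paired analysis was possible because each group is 1 sample. Depth is unknown, so its limit on weak intervals could not be stated.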

Other observations

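The test on other-organ transcription factors was written before its result was seen, on a list made after the data had been seen; those on chromosome X were chosen after. The genes with the most shared intervals in their domain, chosen after their values were seen, were Zfp608 with 9, then Dnm3, Hdac9 and Tbx18 with 7 each. Their domains spanned 2037, 551, 1025 and 1072 kb in that order. Gm11677, Mki67, Pard3b and Zpld1 had 6 shared intervals each. Those with 5 were Gm38821, Lrmda, Mc2r, Mgmt, Npvf, Osr1, Sox11, Sox9, Tcf4, Zfhx3 and Zfp703, and no theme was tested among these genes. Domains of neighbouring genes overlap between them, so the same interval can count for both. An example is the interval on chromosome 18 at 68910369 to 68911743, between Mc2r and Tcf4. In the validation ChIP taken by itself, 44 of 48 limb transcription factor genes had an interval in their domain, against 15.9 expected (adjusted permutation p = 0.0016).

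One hypothesis was that shared intervals gather at developmental transcription factor genes of any organ. Of 63 such genes of other organs, 1 (Pou4f3, 1.59%) had a shared interval in its domain, against 37.5% of limb transcription factor genes. The difference (Fisher's exact p = 4.05e-07) was not matched on domain length. Genes of matched domain length would have given 3.58 of 63, so no excess was seen. A depletion was not shown either (0.279-fold, permutation p = 0.22). This argues against the hypothesis for these 63 genes only. Transcription factor genes in other lists, such as Runx1, Nr4a2 and Grhl2, had a shared interval in their domain. The nearest lay 438, 221 and 0.44 kb from a gene end, in that order. With all validation intervals, 18 of the 63 were occupied against 14.7 expected (1.22-fold, permutation p = 0.37). The excess at limb genes may instead follow chromatin that is active in the limb, whichever protein binds it, and the interval lists alone do not separate this from binding by LMX1B.

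Chromosome X had few intervals: 2 in the first ChIP (1.19 per 100 Mb, against 53.5 on autosomes) and 31 in the validation ChIP (18.5 against 186), the latter 9.94% of the autosomal density (95% exact interval 6.75 to 14.1, exact binomial p = 1.14e-88). Fewer genes on X were argued against, since intervals in gene bodies, per Mb of gene body, had 15.7% of the autosomal density (exact binomial p = 3.95e-22). A lower dose of X in male embryos could contribute, but fewer intervals were listed than it would leave if scores scaled with dose. Halving each autosomal score and dropping those under the lowest listed one would leave 137 validation intervals on X, above the 31 listed (exact binomial p = 2.21e-26). It would leave 21.4 in the first ChIP, above 2 (exact binomial p = 3.98e-07), and 9.35 shared ones, above 1 (exact binomial p = 0.00243). By the criterion first written, the validation value excluded a lower dose. The criterion was tightened after that value was seen, because the unit of the score is not stated and may not scale with dose. A lower dose therefore cannot be told apart from other causes. Repeats, mappability and filtering of X by the authors stay open, and no biological explanation was tested.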
